A study of Bos taurus with 4 samples.

How the data were processed

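Per the labels, mRNA of Holstein cattle was sequenced as read pairs of 150 bp, from libraries prepared from total RNA. The series holds 4 libraries in 2 groups, 2 of mammary tissue and 2 of lymphocytes, and the tissue label placed each library in its group. Both mammary libraries are labelled female and both lymphocyte libraries male, so tissue and sex cannot be told apart and no sex term could be fitted. The titles carry 4 different numbers, so nothing pairs the libraries. Both mammary titles, and neither lymphocyte title, also carry "dup", whose meaning is not given; whether it marks a difference in how the mammary libraries were made or processed is not known, and it cannot be separated from tissue. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Replicate numbers were given in accession order and only name a library.

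The deposited table gives 1 FPKM value (fragments scaled to the transcript's length in kilobases and to the mapped fragments of the library) per Ensembl gene identifier and library, for 24616 identifiers. The submitters' processing notes name Trimmomatic 0.39 (a read trimmer), STAR (an aligner), Cufflinks (a transcript quantifier) and the bovine assembly UMD3.1; their roles, order and settings, the annotation release, the use of strand and the handling of duplicate or multi-mapping reads are not given in the sources used here. All 4 value columns matched the title of 1 sample each, and 0 columns were left unmapped. The table writes a zero in 2 forms, with 1 decimal or with 6; 5279 rows were zero in all 4 libraries, and 3344 of these had the short form throughout. What separates the forms is not given, and both were read as 0. An exact 0 may be a failed estimate; 1 row was listed at 0 in mammary replicate 2 while all the other libraries were at 10 FPKM or more, and 0 rows were so in any other library.

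The table pairs no gene name with its identifiers, and 0 of the 24616 identifiers were found in the RefSeq gene table at hand (assembly ARS-UCD2.0, 37063 genes), which lists no Ensembl identifiers. Gene names, chromosome positions and row lengths are therefore not reported here. The 34 lists of marker and pathway genes fixed beforehand could not be matched to rows, so none was tested, and neither was the planned comparison without the X chromosome. The rule for named genes asked for rows with a symbol; it was applied to identifiers instead, and the 2 rows with the largest difference in each direction are named.

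FPKM keeps no read count. Ratios in rows below 0.08 FPKM in both libraries of a pair were scored against the steps that whole fragments would give. The tolerance was 0.015 on the log2 scale, and the offset with the most ratios on steps was taken. Even there, only a minority fell on steps. That choice puts the offset above the average by construction, and no ratios without steps were scored, so the relative depths below are not established. The best-scoring offset put the depth of mammary replicate 2 at 1.09 times that of mammary replicate 1 (63 of 337 rows on steps, against 52 for the next offset and 13.2 on average over offsets), and that of lymphocyte replicate 2 at 1.22 times that of lymphocyte replicate 1 (76 of 453 rows, against 68 and 19.5). The next offsets lay about a factor of 2 away and were not excluded. Absolute depth is unknown, so no counting interval or detection limit is given and no count test was run.

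Values were compared as log2(FPKM + 1), with the FPKM as deposited. Rows at 1 FPKM or more in at least 2 of the 4 libraries were tested, 12311 in all. The test was limma's moderated test (limma 3.58.1, R 4.3.3; two-sided, with a mean-variance trend and Benjamini-Hochberg adjustment, threshold 0.05), fitted to all 4 libraries with tissue as the only term. Fold changes on this scale understate the change of low rows. With 2 residual degrees of freedom per row, limma's estimate of the prior degrees of freedom was infinite, so a row's own spread did not enter its test; each row was given the spread typical of its level, 0.84 on the log2 scale for the median row. The very small p-values below rest on that pooled spread. As the main fit applied no scaling, the pooled spread also holds shifts shared by most rows of a library. The median difference between replicates was -1.05 in mammary tissue and 0.40 in lymphocytes. After median-of-ratios scaling the prior had 2.33 degrees of freedom and a typical spread of 0.28, and that fit is given beside the main one. The step was run on simulated data with the observed means of the 12311 rows and the pooled spread that the test itself assumes. Of 50 rows changed by a log2 difference of 1, 0 were called. Of 50 each changed by 2, 4 and 6, 6, 40 and 50 were called, all in the right direction. There were 0 false calls among the unchanged rows, which cannot show how the test fares where a row's own spread differs from the pooled one. The simulation drew rows independently, so it does not carry a shift shared by all rows of a library.

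Alternatives covered the pseudocount, the filter, the scaling (rescaling to a common FPKM total, median of ratios, quantile), the variance model, the threshold and leaving out each library. Test, filter, lists, naming rule and alternatives were fixed before the data were examined, except for leaving out libraries after median-of-ratios scaling, which was added afterwards. Descriptive values were computed with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.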

Results

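Gene expression was measured by RNA sequencing in 2 bovine sources, mammary gland tissue and lymphocytes, with 2 libraries of each. The mammary gland is a secretory organ built from epithelium, stroma and vessels, whereas lymphocytes are immune cells, and the series compares the transcriptomes of both. The deposited FPKM values summed to 1536182 and 1384625 in mammary replicates 1 and 2 and to 828745 and 964825 in lymphocyte replicates 1 and 2. Between 15844 and 17953 of the 24616 gene rows were above 0 in a library. Rows are given by Ensembl identifier, since the identifiers were not paired with gene names or positions here. The mammary libraries came from females and the lymphocyte libraries from males, so each difference below is one between both tissue and sex.

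A common set of 8305 rows was expressed at 1 FPKM or more in all 4 libraries. A further 968 rows reached that level in both mammary libraries and lay below it in both lymphocyte libraries, and 693 rows showed the opposite. These sets depended on the scaling: after median-of-ratios scaling they held 1611 mammary and 489 lymphocyte rows, and after rescaling each library to a common FPKM total the balance reversed, to 746 and 1222 rows. At a higher level, 94 rows were at 10 FPKM or more in both mammary libraries and below 1 FPKM in both lymphocyte libraries, and 47 rows showed the opposite. Of these, 28 mammary rows were listed at 0 in both lymphocyte libraries, against 1 lymphocyte row listed at 0 in both mammary libraries. The counts at 10 FPKM were taken as deposited and not repeated after scaling, so their balance may depend on it too.

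The summed FPKM was concentrated in few rows in both sources, and more so in the mammary libraries once the 10 highest rows were counted. The single highest row took its largest share, 30.5%, in lymphocyte replicate 1. FPKM is per kilobase and row lengths are not known, so these shares are not shares of fragments. The 20 highest rows held 79.2% and 88.1% of the summed FPKM in mammary replicates 1 and 2, and 63.7% and 57.6% in lymphocyte replicates 1 and 2. With 2 libraries per source, no permutation test of this difference can give a two-sided p below 0.33. Of the 20 highest rows, 11 were among the 20 highest in every library. These 11 rows held between 52.8% and 74.0% of the summed FPKM of a library. The 20 highest rows overlapped by 17 between the lymphocyte libraries and by 13 between the mammary libraries.

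**Figure D1:**
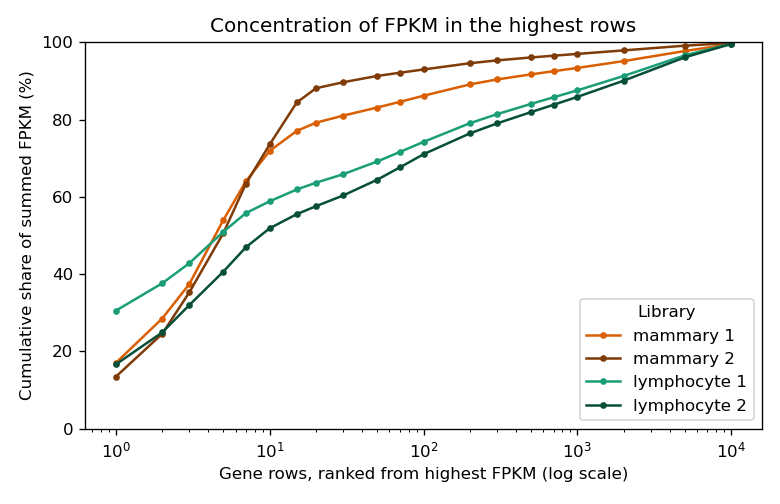
Cumulative share of the summed FPKM (%, vertical axis) held by gene rows ranked from the highest (log horizontal axis), with 1 line per library. The mammary lines lie above the lymphocyte lines at 20 rows, at 79.2% and 88.1% against 63.7% and 57.6%.

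The 4 libraries separated by source, and the mammary replicates were less alike than the lymphocyte replicates. Across the 12311 tested rows, log2(FPKM + 1) correlated with a Pearson r of 0.95 (Spearman rho 0.94) between the lymphocyte replicates and 0.87 (rho 0.85) between the mammary replicates. Between sources, r ranged from 0.54 to 0.62. These correlations run across genes, which are not independent replicates. Mammary replicate 2 lay below mammary replicate 1 in most rows, with a median difference of -1.05 on the log2 scale and quartiles of -1.43 and -0.64. Lymphocyte replicate 2 lay above lymphocyte replicate 1 by a median of 0.40. A set of 19 rows was more than 32-fold higher in mammary replicate 2 than in mammary replicate 1. These rows reached up to 148249 FPKM in replicate 2 and held 31.0% of its summed FPKM, against 0.31% in replicate 1. Their highest lymphocyte value was 38.1 FPKM. No 2 libraries held the same values: within 0.01 FPKM, the lymphocyte replicates agreed in 346 of the 12311 rows and the mammary replicates in 38.

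**Figure D2:**
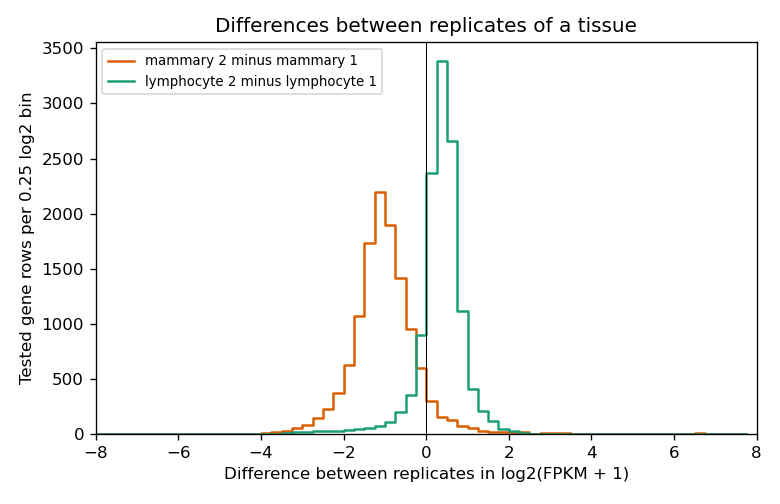
Differences between the replicates of each source in log2(FPKM + 1) (horizontal axis), as the number of tested rows per bin of 0.25 (vertical axis). The mammary curve is centred at -1.05 and the lymphocyte curve at 0.40.

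Of the 12311 rows tested, 2363 differed between mammary tissue and lymphocytes at an adjusted p below 0.05 by limma's moderated test. Of these, 1051 were higher in mammary tissue and 1312 higher in lymphocytes. The median called row differed by 2.57 on the log2 scale when higher in mammary tissue and by 2.63 when higher in lymphocytes. The smallest difference of a called row was 1.016. Differences above 5 on the log2 scale were found in 63 rows higher in mammary tissue and 34 rows higher in lymphocytes. The median of all tested rows was itself lower in mammary tissue, at -0.81 on the log2 scale, so the balance of directions depended on the scaling. Mammary tissue held 44.5% of the calls as deposited. It held 60.6% after median-of-ratios scaling, which moves the median row to -0.01 and called 1511 rows higher in mammary tissue and 981 higher in lymphocytes. It held 15.9% after each library was rescaled to a common FPKM total (1079 and 5710 rows), and 46.2% after quantile normalization (1374 and 1598 rows). A core of 1688 rows was called in the same direction under all 4 scalings, 847 higher in mammary tissue and 841 higher in lymphocytes. Of the mammary core, 716 rows lay below 1 FPKM in both lymphocyte libraries, and of the lymphocyte core, 240 lay below 1 FPKM in both mammary libraries. By contrast, 170 rows of the mammary core were at 10 FPKM or more in both mammary libraries, against 560 rows of the lymphocyte core in both lymphocyte libraries. These levels of the core were FPKM as deposited and were not recounted under the other scalings. Median-of-ratios scaling divided mammary replicate 2 by 0.449 and lymphocyte replicate 2 by 1.65, so the contrast in level may depend on the scaling. The core was lost under median-of-ratios scaling when either lymphocyte library was left out. In such a fit the spread comes from the mammary replicates alone, which differed more than the lymphocyte replicates. The loss therefore does not show that the core rests on the lymphocyte libraries. The number of calls also depended on the filter and on which libraries were fitted. Without the filter on low values 5 rows were called, 4 higher in mammary tissue and 1 higher in lymphocytes. It was 3828 without mammary replicate 1, 1586 without mammary replicate 2, 109 without lymphocyte replicate 1 and 102 without lymphocyte replicate 2; in each case the lone library of a source was assumed to vary like the replicates of the other.

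**Figure D3:**
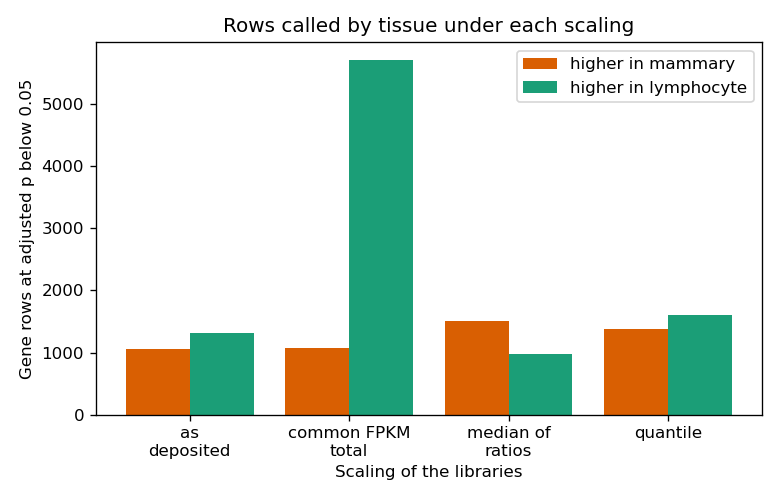
Number of gene rows at an adjusted p below 0.05 by limma (vertical axis, from 0) that were higher in mammary tissue or in lymphocytes, under 4 scalings of the libraries (horizontal axis). The mammary bars range from 1051 to 1511 rows and the lymphocyte bars from 981 to 5710 rows.

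The 2 largest differences in each direction belonged to rows that were far lower in the other source. These rows also varied strongly between the replicates of the source in which they were high. ENSBTAG00000039787 was at 1183 and 48464 FPKM in mammary replicates 1 and 2 and at 1.56 ± 0.40 FPKM (SD, n = 2) in lymphocytes. Its log2 difference was 11.54 (SE 0.89, limma adjusted p = 5.2e-34). ENSBTAG00000007695 was at 1481 and 148249 FPKM in mammary replicates 1 and 2 and at 5.85 ± 0.90 FPKM (SD, n = 2) in lymphocytes, a log2 difference of 11.09 (SE 0.91, limma adjusted p = 1.1e-30). In the opposite direction, ENSBTAG00000011961 was at 2467 and 283.4 FPKM in lymphocyte replicates 1 and 2 and at 0.32 ± 0.19 FPKM (SD, n = 2) in mammary tissue. Its log2 difference was -9.32 (SE 0.87, limma adjusted p = 1.5e-23). ENSBTAG00000018785 was at 1121 and 90.4 FPKM in lymphocyte replicates 1 and 2 and at 0.195 ± 0.0022 FPKM (SD, n = 2) in mammary tissue, a log2 difference of -8.07 (SE 0.86, limma adjusted p = 1.0e-17). The size of these differences rested on single libraries: the log2 differences were 14.22 and 14.41 for both mammary rows without mammary replicate 1 and 8.86 and 7.76 without mammary replicate 2, and -7.76 and -6.26 for both lymphocyte rows without lymphocyte replicate 1 and -10.88 and -9.87 without lymphocyte replicate 2. In the fit after median-of-ratios scaling, where a row's own spread counts, all 4 kept their direction with limma adjusted p-values of 0.032, 0.048, 0.019 and 0.033 in the same order, and standard errors between 1.23 and 2.70. Under that scaling 0 rows passed by limma without either lymphocyte library, so these 4 calls were lost as well; the lowest adjusted p-values were 0.091 without lymphocyte replicate 1 and 0.076 without lymphocyte replicate 2, and 2787 and 2967 rows had an unadjusted p below 0.05. In the fits without a lymphocyte library, the spread came from the mammary replicates alone. Without the filter on low values none of the 4 passed, at limma adjusted p-values of 0.089, 0.10, 0.072 and 0.097.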

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

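The 4 named rows kept their direction under all 14 alternatives run; they missed the threshold without the filter on low values, and ENSBTAG00000018785 also missed it without mammary replicate 2 (log2 difference -8.07, limma adjusted p = 0.053). Over these alternatives the limma adjusted p of the 4 rows, in the order of the report, ranged from 6.4e-50 to 0.089, from 3.5e-46 to 0.10, from 2.2e-34 to 0.072 and from 6.9e-27 to 0.097. The number of rows called moved far more than their direction. Without the filter, 5 rows were called (4 higher in mammary tissue and 1 in lymphocytes), and the prior then had 4.67 degrees of freedom in place of an infinite number; the rows added had low values and many zeros. A filter at 5 FPKM left 1370 calls, of which 383 were higher in mammary tissue, with fewer rows tested. Rescaling to a common FPKM total gave 6789 calls, of which 5710 were higher in lymphocytes, with the median row at -1.33. An adjusted p below 0.01 left 771 rows higher in lymphocytes. Leaving out each library gave 102 to 3828 calls, with 37 to 1187 higher in mammary tissue and 58 to 2754 higher in lymphocytes; of the 2363 rows, 2098 and 1300 were called again without mammary replicates 1 and 2, and 1 row turned. Without lymphocyte replicates 1 and 2, 109 and 102 rows were called again. After median-of-ratios scaling, an alternative added after seeing the data, leaving out mammary replicates 1 and 2 gave 2461 and 1518 calls, and leaving out lymphocyte replicates 1 and 2 gave 0 each by limma, with 2787 and 2967 rows at an unadjusted p below 0.05. With a library left out, the spread came from the replicates of the other source alone. Pseudocounts of 0.1 and 5, median-of-ratios and quantile scaling and a fit without the trend left all 3 counts within 1.5 times. A 2-fold minimum could remove no call, because the smallest called difference was 1.016 on the log2 scale. The planned tests of the gene lists and of rows off the X chromosome were not run, as no names or positions could be assigned. Depth is unknown, so nothing can be said of how counting error limits low rows.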

Other observations

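All tests in this part were chosen or given their final form after the result was seen. Relative to the median row, the large differences between replicates ran mostly in one direction in each source. By that measure, 90 of the 12311 tested rows were more than 8-fold higher in mammary replicate 2 and 20 in replicate 1. Beyond 32-fold the numbers were 30 and 0. The mammary direction at 8-fold rests on this centring, since the median row lay at -1.05. Without it, more rows were over 8-fold lower than over 8-fold higher in mammary replicate 2. With the centring, a row had to fall further than it had to rise to be counted. Adding 1 to the FPKM limits how far a low row can fall, so low rows could not count as higher in mammary replicate 1. This held at 8-fold and at 32-fold alike, so the asymmetry was partly fixed in advance. Relative to their own median row, 85 rows of the lymphocyte replicates were more than 8-fold higher in replicate 1 and 2 rows in replicate 2. Those 85 rows had median levels of 46.0 and 5.19 FPKM in lymphocyte replicates 1 and 2. Of them, 23 (27.1%) lay below 1 FPKM in both mammary libraries. The share among other rows of the same lymphocyte level was not computed, so whether 27.1% is high is not known. The labels give no group that separates the replicates of a source.

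One hypothesis was that the rows that raise mammary replicate 2 are rows low in lymphocytes. Among all rows with a mammary mean of at least 8 FPKM, 92 were more than 8-fold higher in mammary replicate 2 relative to the median row, and 45.7% of these lay below 1 FPKM in both lymphocyte libraries. The share was 8.85% among the other 3944 rows (two-sided Fisher's exact test, p = 1.1e-19, over rows, which are not independent), but these were held only to the same floor. Rows of the same level in mammary replicate 1 had a share of 23.3%. The control in the opposite direction, the 25 rows more than 8-fold higher in mammary replicate 1, had a share of 64.0%. Rows of the same level in mammary replicate 2 had a share of 18.5%. A low lymphocyte level thus does not single out mammary replicate 2, and the test decides nothing about that library. The cause of the difference between the mammary replicates stays open, a batch difference included.

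The lower level of most rows in mammary replicate 2, by a median of -1.05 in log2(FPKM + 1), was set against 2 technical explanations. More lymphocytes in mammary replicate 1 would not raise there the rows that lymphocytes lack. The 2983 rows below 1 FPKM in both lymphocyte libraries and at 0.1 FPKM or more in both mammary libraries had a median log2 ratio of FPKM, without a pseudocount, of -1.70 for replicate 2 over replicate 1 (95% bootstrap interval -1.78 to -1.64). On the same scale and with the same floor, the other 11184 rows had a median of -1.43. Rows below 1 FPKM in lymphocytes were thus lower too, and by no less than the others. With a mammary floor of 0.1 FPKM, such a row can still be higher in lymphocytes than in mammary tissue. The test therefore cannot decide whether lymphocytes caused the general shift, and other blood cells were not tested. The second explanation was that a few very high rows take the fragments of the others. For a shift of -1.05 they would need to hold at least 50% of the fragments, and more for the medians without a pseudocount. The 19 rows more than 32-fold higher in replicate 2 held 31.0% of its summed FPKM. Rows that rose less were not counted, and the 20 highest rows held 79.2% of the summed FPKM in replicate 1 and 88.1% in replicate 2. Without row lengths these cannot be turned into shares of fragments, so the explanation stays open. No biological explanation was tested.

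Lymphocyte-rich rows, more than 32-fold above the mammary mean, showed how much a filter can decide. Against rows of the same mammary level that passed the filter on low values and lay below 1 FPKM in lymphocytes, their log2 FPKM ratio, without a pseudocount, was shifted toward mammary replicate 1 by 1.04 (95% bootstrap interval 0.42 to 1.55, 38 rows matched). That filter admits such comparison rows only if both mammary values reach 1 FPKM, which removes the rows that fell in replicate 2. With both kinds of row held to 0.1 FPKM in both mammary libraries, the shift was -0.0089 (-0.17 to 0.17, 92 rows matched). The first value may therefore be a product of the filter. Neither value decides whether mammary replicate 1 held more lymphocytes, because the rows were chosen for a low mammary level, which limits the share that could be seen, and the floor of 0.1 FPKM still leaves out rows that fell further. The 92 rows stood at a median of 2.76% of their lymphocyte level in mammary replicate 1 and 0.83% in replicate 2.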
